A study of Rattus norvegicus with 84 samples.

How the data were processed

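Total RNA of 84 cultured germ cell samples was measured, each on 1 array of a rat Agilent platform with 62976 spots. Per the labels' protocols, cells were isolated from young or aged Brown Norway rats and cultured in medium with 5% serum for 13 h at 32 °C. They then received EUK-134 or medium alone, and 30 min later saline or SIN-1. From 0.5 µg of RNA, Cy3-labelled cRNA was prepared with a one-colour kit, per the labels' protocols. The labels give age, cell type, treatment and time, which made 20 groups of 4 or 5 arrays. The sample titles carry 10 codes, 5 for each age, numbered 20 to 24 and shared across treatments and cell types. The labels do not say what a code is, and they do not say that arrays of a group are separate cultures, so the p-values measure the spread between these samples. Replicates are named here by the number of their code.

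The values used were the processed signal intensity of each spot, background-corrected by the authors' scanner software and not scaled between arrays, per the file headers. These name Feature Extraction 11.5.1.1, while the submitters' processing notes name version 9.1. The median and background median intensity of each spot are also deposited, and served an alternative background correction. The plan named the mean signal for that alternative, which the array files lack, and the median signal took its place. A series matrix of log2 values is deposited too, with 30505 lines and a median between 6.6544 and 6.6545 in each of its 84 columns. Its log2 values correlated across probes with the log2 processed intensity of the same array (Pearson r from 0.99612 to 0.99997), where probes are not independent replicates. The equal medians are what quantile normalization over all arrays gives, and no header or label states that step. The matrix served as an alternative. The headers of 7 arrays, all on slide 9, carry a second protocol variant.

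Control spots (4259) were left out, and spots marked as non-uniform or as population outliers were set missing on their array. The other 58717 spots were averaged to 30367 probes, where 166 of 2550828 values were missing. The files hold no gene names, in contrast to what the plan assumed. Names came from matching the accession in the probe annotation of the files to a RefSeq gene table (assembly GRCr8, used for names and for which genes neighbour each other). Of the probes, 17998 matched a symbol (15154 symbols) and 12369 did not. Each array's log2 processed signal was reduced by the log2 of its 75th percentile (718 to 2037 in pachytene spermatocytes, 342 to 1563 in round spermatids). A probe was kept when it was well above background on at least 3 arrays of at least 1 group. The kept probe with the highest mean level stood for its gene, and probes without a symbol stayed as features. This left 21291 features for pachytene spermatocytes (11935 with a symbol), 21158 for round spermatids (11906) and 22164 for both (12432).

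The 42 arrays of a cell type entered 1 limma fit with 10 group means and moderated statistics, and all arrays entered a fit with 20 means for the cell types. Without a block these fits treat arrays of the same title code as independent, and age differs only between codes. The p-values for age do not allow for this. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, in 19 main comparisons. The design, the 24 gene lists and the alternatives were fixed before the data were examined. Lists were tested with camera (preset correlation 0.01, and with the correlation estimated), adjusted over all lists and comparisons of a cell type, 456 tests in all. No call by the preset correlation held with the estimated correlation. For each call the list's median, mean and test had the same sign. Medians of called lists were recomputed under the other scalings, without a test, and those at 0.5 times the reported median or less, or with another sign, are given. Named genes were, for each comparison, the 8 largest rises and 8 largest falls among called genes with a symbol and up to 2 called members of each list. With fewer than 6 calls, all calls and the 3 genes with the smallest p were named. The rule was applied to the fits without and with the title code as a block, and the text names a part of the genes it gave. A fold is given as a bound, "at least", where 0 arrays of the lower group were well above background. The lower group's values were then raised to the lowest level called well above background on each array. The bound allows for background and not for the spread between arrays, so it is no minimum change for a gene that did not pass.

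Arrays that share a title code were read as coming from 1 cell preparation. This was checked from the correlation of arrays after group means and slide were removed. In pachytene spermatocytes pairs with the same code had a mean r of 0.293, 65 of 73 pairs exceeded 0.1 (lowest -0.158), and pairs of other codes of the same age had a mean of -0.120. With slide left in, as in the block fits reported, the mean was 0.130, 38 of 73 pairs exceeded 0.1 and the lowest was -0.573. In round spermatids the mean was 0.0099 and 24 of 73 pairs exceeded 0.1. The pairing was therefore not uniform, and the counts with and without the block had been seen when both were kept. Blocked values are given beside the unblocked values of treatments in pachytene spermatocytes. Genes named from a fit with the block were picked on the pairs of that block. Counts of pairs in the same direction are therefore no separate support for them. In round spermatids the block gave 0 genes for the treatments, as did the fit without it, and 9 spermatid list calls passed no longer with it, or with the number as a block for age (adjusted p from 0.0531 to 0.0838). Numbers shared by the ages are not the same code, so a block by number is given only with the alternatives for age, and pairs by number are not counted beside age genes.

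The fit was tested on simulated arrays with the mean and residual spread of each real feature, independent noise and no slide effect, with 100 genes changed by 2-fold and 100 by 4-fold in each comparison, over 21241, 21101 and 22054 features in pachytene spermatocytes, round spermatids and both. The percent recovered at 2-fold and 4-fold in pachytene spermatocytes was 65 and 95 for age at 13 h, 64 and 93 for age at 17 h, 64 and 91 for SIN-1 in young cells and 78 and 92 for SIN-1 in aged cells. It was 49 and 78 for the interaction, 69 and 94 for pretreatment in young cells, 61 and 87 for pretreatment in aged cells, 83 and 98 for EUK-134, and 91 and 99 for culture time. In round spermatids it was 67 and 94, 67 and 95, 61 and 94, 72 and 94, 45 and 81, 63 and 97, 66 and 91, 83 and 99, and 86 and 100 in the same order. For the cell types it was 100 at both folds. False calls ran from 3 to 15 per comparison. Where fewer genes change than were simulated, the cut-off after adjustment is stricter, so recovery would be lower than given here.

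The alternatives were normexp background correction (offset 50), quantile normalization, no filter on dim probes, every probe tested, slide as a block, slide with array row, the replicate block, only the groups compared, the deposited matrix, leaving out each number, and a minimum of 1.5-fold. Alternatives chosen after seeing the data were the replicate block with slide, leaving out the 3 spermatid arrays at the marker level of the other age, leaving out the array labelled pachytene young SIN-1 replicate 22, leaving out the pachytene array of the fewest probes above background, leaving out slide 9, and slide as a block with number 24 left out. The array labelled young SIN-1 replicate 22 was picked for its level of Cyp2c7, a gene called by age, and for its low share of probes above background, so the counts without it are not independent of the age result. The array of the fewest probes was added last, as its counterpart. The analysis used R 4.3.3, limma 3.58.1, data.table in version 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.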

Results

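RNA of 84 cultured germ cell samples of Brown Norway rats was measured on 84 one-colour Agilent arrays. The series concerns how male germ cells of young and of aged animals respond to oxidative stress. The cells were pachytene spermatocytes, which are in meiotic prophase, or round spermatids, which follow meiosis, with 42 arrays each. Each cell type came from 2 ages under 5 conditions: saline at 13 h, saline at 17 h, SIN-1, EUK-134, and EUK-134 followed by SIN-1. SIN-1 is a pro-oxidant that releases the precursors of peroxynitrite, and EUK-134 is an antioxidant that mimics catalase and superoxide dismutase. The 4 aged saline groups held 5 arrays each, and the other 16 groups held 4. Between 64.0% and 85.6% of the probes lay well above background on the pachytene arrays (median 73.7%), and between 63.1% and 78.7% on the spermatid arrays (median 72.5%). No spot was saturated. The number of arrays limits the precision of every value. Each of the 12 slides held 7 arrays of 1 cell type, and slide accounted for most of the first principal component (R² = 0.973 in pachytene spermatocytes, 0.965 in round spermatids). This component held 31.3% and 32.0% of the variance. In pachytene spermatocytes the second component, with 12.3% of the variance, followed the code in the sample titles (R² = 0.896). Each code belongs to 1 age, and age alone had R² = 0.542 on this component.

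The comparison of aged with young pachytene spermatocytes under saline at 13 h (n = 5 and 4) asked which transcripts differed with age before the treatment window. Of 21291 features, 6 rose and 6 fell in aged cells in limma, and 2220 had an unadjusted p under 0.05, against 1065 by chance. Serinc2, a serine incorporator, fell from a mean normalised log2 level of -1.31 ± 0.19 (SD, n = 4) to -3.68 ± 0.34 (SD, n = 5), a log2 difference of -2.37 ± 0.19 (SE, adjusted p = 2.39e-10). Zcchc17, a zinc knuckle protein of the nucleolus, rose by 2.90 ± 0.25 on the log2 scale (adjusted p = 1.4e-09). Cxadr, the coxsackievirus and adenovirus receptor, fell by 1.76 ± 0.27 (adjusted p = 0.000806), and Csrp2 fell by 1.17 ± 0.22 (adjusted p = 0.0331). Oit3, not well above background on any aged array, was at least 2.27-fold lower (adjusted p = 0.0483). Cyp2c7, a cytochrome P450, rose by 3.15 ± 0.58 (adjusted p = 0.0201). Its young levels, from -8.37 to -7.48, overlapped those at 17 h, where no young array was well above background. The size of this rise is therefore uncertain. The monocyte chemokines Ccl2 and Ccl7 rose by 1.76 ± 0.36 (adjusted p = 0.0483) and 1.72 ± 0.34 (adjusted p = 0.0429). Pdlim4 fell by 0.79, Fezf2 rose by 0.80 and Pias3 rose by 0.50 (adjusted p 0.0498, 0.0489 and 0.0498). Without number 20, 21 or 24 in both ages, 5 genes passed each time. The array labelled pachytene young SIN-1 replicate 22, which enters the spread, had a Cyp2c7 level of -4.72, against -7.48 on the next highest of the other young arrays, and 64.1% of its probes well above background. Without this array, chosen after its Cyp2c7 level was seen, 31 genes passed. Without the pachytene array of the fewest probes above background (64.0%, labelled aged EUK-134 then SIN-1 replicate 24) 10 passed. A fit with slide gave 48 rises and 118 falls.

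At 17 h under saline (n = 5 and 4), 14 genes rose and 85 fell in aged pachytene spermatocytes, and 2451 features had an unadjusted p under 0.05. Most title codes were the same as at 13 h, so this comparison is not independent of that at 13 h. Serinc2 fell by 2.23 ± 0.19 (adjusted p = 1.49e-09), Cxadr fell by 2.11 ± 0.27 (adjusted p = 1.82e-05) and Zcchc17 rose by 2.69 ± 0.25 (adjusted p = 1.06e-08). Hspd1 and Hspe1, the mitochondrial chaperonin and its cochaperonin, fell by 1.41 ± 0.28 (adjusted p = 0.0119) and 1.02 ± 0.18 (adjusted p = 0.00653). At 13 h their log2 differences were -1.21 (adjusted p = 0.0739) and -0.87 (adjusted p = 0.0524). Cycs, cytochrome c, fell by 0.54 (adjusted p = 0.0494). Inha, the alpha subunit of inhibin, fell by 0.95 ± 0.22 (adjusted p = 0.0422), and the growth factor Ptn fell by 1.25 ± 0.29 (adjusted p = 0.0394). Pecr and Prickle1 fell by 1.33 and 1.32. Cfp and Klhl4, not well above background on any aged array, were at least 2.07-fold (adjusted p = 0.0237) and 2.12-fold lower (adjusted p = 0.0264). Among the rises were Thbd, thrombomodulin (2.36 ± 0.45, adjusted p = 0.00893), G0s2, an inhibitor of the triglyceride lipase (1.66 ± 0.29, adjusted p = 0.0057), Ccl7 (1.56 ± 0.34, adjusted p = 0.0283), Mark1 (1.08), Fezf2 (0.90) and Ptpru (0.73). Cyp2c7, not well above background on any young array at 17 h, was at least 4.88-fold higher in aged cells (adjusted p = 0.00642). Leaving out number 20, 21, 22, 23 or 24 gave 6, 6, 54, 62 or 12 genes, and without slide 9, whose headers carry a second protocol variant, 56 passed. A fit with slide gave 67 rises and 211 falls.

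**Figure D1:**
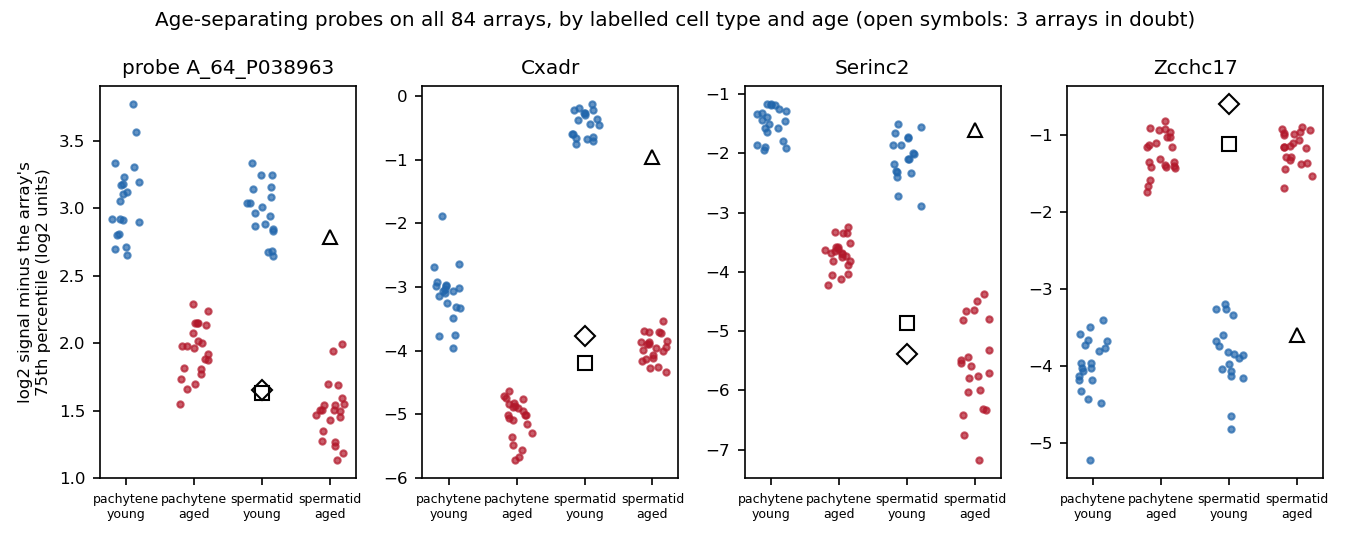
Normalised log2 level (vertical axis, log2 signal minus the 75th percentile of the array) of Cxadr, Serinc2, Zcchc17 and the probe A_64_P038963 on all 84 arrays, by labelled cell type and age. Each point is an array, and the open symbols are 3 spermatid arrays at the level of the age opposite to their label.

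Several gene lists fixed before the data were examined shifted with age in pachytene spermatocytes, by camera with a preset correlation between genes. The list of inflammation and NF-kB genes had a median log2 difference of 0.39 at 13 h, with 16 of 17 members above 0 (adjusted p = 1.56e-05, and adjusted p = 0.629 with an estimated correlation). Ccl2 rose, and 6 members passed adjusted over the list alone; Cxcl1 and Cxcl2 had values of 1.61 (adjusted p = 0.119) and 2.34 (adjusted p = 0.096). At 17 h its median was 0.55 (0.23 with normexp background correction), with 14 of 17 above 0 and 7 members past adjusted over the list alone (adjusted p = 0.000185, and adjusted p = 0.774 with an estimated correlation). The heat shock list had a median of -0.20 at 13 h with 13 of 15 members below 0 and 3 passing adjusted over the list alone (adjusted p = 0.000592, and adjusted p = 0.418 with an estimated correlation). At 17 h its median was -0.21 (adjusted p = 6.62e-05, and adjusted p = 0.418 with an estimated correlation), Hspd1 and Hspe1 fell, and 5 members passed adjusted over the list alone. Antioxidant enzymes had a median of -0.13 at 13 h, with 21 of 27 below 0 and 7 passing adjusted over the list alone (adjusted p = 0.00871). The same list had adjusted p = 0.85 with an estimated correlation and adjusted p = 0.0996 with slide as a term. Prdx3, a mitochondrial peroxiredoxin in this list, had a value of -0.82 (adjusted p = 0.105). Immediate early genes had a median of -0.20 at 17 h (-0.0897 with normexp) with 17 of 23 below 0 (adjusted p = 0.00407, and adjusted p = 0.733 with an estimated correlation). The mismatch and nucleotide excision repair list had a median of 0.17 at 17 h with 12 of 12 members above 0 (adjusted p = 0.0246, and adjusted p = 0.629 with an estimated correlation).

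Markers of other cell types moved with these age comparisons. A difference in the share of such cells between the ages was not tested, so the age genes cannot be assigned to the germ cells alone. Sertoli cell markers had a median of -0.49 at 13 h, with 15 of 17 below 0 and 4 past adjusted over the list alone (adjusted p = 1.84e-05, and adjusted p = 0.453 with an estimated correlation). At 17 h the Sertoli list had adjusted p = 7.13e-05 (adjusted p = 0.468 with an estimated correlation), Inha fell, and 6 members passed adjusted over the list alone. Round spermatid markers had medians of -0.27 at 13 h, with 25 of 27 below 0, and -0.31 at 17 h. Their adjusted p was 0.00584 and 0.000445, and adjusted p = 0.874 and 0.857 with an estimated correlation. Meiotic prophase markers had medians of 0.13 and 0.16 (adjusted p = 0.0251 and 0.0227, and adjusted p = 0.85 at both times with an estimated correlation). Spermatogonial markers had a median of -0.31 at 17 h, and -0.14 with normexp background correction (adjusted p = 0.0227, and adjusted p = 0.418 with an estimated correlation).

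The response to the pro-oxidant was tested as SIN-1 minus saline at 17 h, in young (n = 4 and 4) and in aged pachytene spermatocytes (n = 4 and 5). In young cells 1 feature rose, 0 fell in limma, and 1069 had an unadjusted p under 0.05. It was the probe A_64_P116467, which has no gene symbol and rose by 1.06 ± 0.18 (adjusted p = 0.0289). In aged cells 1 gene rose, 0 fell, and 497 had an unadjusted p under 0.05. This gene was Apold1, an early response gene known from endothelium, which was not well above background on any saline array and was at least 3.26-fold higher under SIN-1 (adjusted p = 0.000186, 4 of 4 pairs). In young cells Apold1 had a bound of at least 2.37-fold and did not pass (adjusted p = 0.105). In aged cells Tcf21 had a value of 1.80, and Dusp14, not well above background on any saline array, a bound of at least 2.05-fold, each with adjusted p = 0.122. Without number 20, 21 or 22, no feature passed in young cells, and leaving out each number in turn gave 1 gene in aged cells. In young cells 2 passed without the array labelled young SIN-1 replicate 22, 1 without the array of the fewest probes above background, 11 without slide 9, and 3 with slide as a term.

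With the title code as a block, 6 features rose and 98 fell under SIN-1 in young cells, and 1 rose and 0 fell in aged cells, where 1069 had an unadjusted p under 0.05. In young cells with this block Apold1, not well above background on any saline array, passed (adjusted p = 0.00118, at least 2.37-fold by the bound). With the block Adamts1, a secreted protease, rose by 1.28 ± 0.24 (adjusted p = 0.0133) and the cytokine Il6 by 0.87 ± 0.19 (adjusted p = 0.0306). Among the falls with the block were Mex3b (-1.14), Bmyc (-1.12), Amhr2, the receptor of anti-Müllerian hormone (-1.09), Pard6b, a cell polarity gene (-1.08), Ralb, a small GTPase (-0.98), Ripk1, a kinase of cell death signalling (-0.96), and Dusp1 (-0.83). Hspd1 fell by 0.73 ± 0.16 (adjusted p = 0.0336) and Prdx3 by 0.52 ± 0.12 (adjusted p = 0.0426) with the block. Without the block their adjusted p was 0.947 and 0.955. These genes moved in the same direction in 4 of 4 pairs, the pairs on which the block fit picked them. Over all the alternatives the adjusted p ran from 0.00118 to 0.668 for Apold1, 0.00511 to 0.992 for Adamts1, 0.00559 to 1 for Il6, 0.0158 to 1 for Hspd1 and 0.0331 to 1 for Prdx3. In aged cells Apold1 passed with the block (adjusted p = 4.39e-06, at least 3.26-fold by the bound), and over the alternatives its adjusted p ran from 4.24e-06 to 1.

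The interaction asked whether the SIN-1 response differed between the ages. In pachytene spermatocytes 0 genes passed in limma, with 119 at an unadjusted p under 0.05, and the smallest adjusted p was 1 for all genes, Apold1 included. With the block 0 passed, and 188 had an unadjusted p under 0.05. The genes with the smallest p were Dusp1, a phosphatase of MAP kinases (1.06 ± 0.34), Slc16a10 (1.17 ± 0.36) and Dusp14 (1.20 ± 0.39, but -0.09 with normexp background correction). Without number 24, 1 gene passed. The hypoxia and glycolysis list had a median interaction of 0.09, with 18 of 22 members above 0 (adjusted p = 0.00407, and adjusted p = 0.629 with an estimated correlation). Immediate early genes had a median of 0.18 (0.0533 with normexp), with 18 of 23 above 0 (adjusted p = 0.0182, and adjusted p = 0.85 with an estimated correlation), and adjusted p = 0.0896 with slide as a term.

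Among the lists under SIN-1, oxidative phosphorylation had a median of 0.10 in young cells with 27 of 32 members above 0 (adjusted p = 0.00605, and adjusted p = 0.85 with an estimated correlation), which turned to -0.02 both with quantile normalization and with the deposited matrix. In aged cells its median was 0.05, with 26 above 0 (adjusted p = 0.0235, and adjusted p = 0.857 with an estimated correlation). It was 0.0056 with quantile normalization and 0.0043 with the deposited matrix, and had adjusted p = 0.1 with the title code as a block. Nrf2 targets, the genes of the main antioxidant transcription factor, had a median of -0.16 in young cells (adjusted p = 0.0323, adjusted p = 0.85 with an estimated correlation and adjusted p = 0.235 with slide as a term). Sertoli markers moved with both responses, with medians of -0.42 and -0.30 and 12 of 17 below 0 in each. Their adjusted p was 0.0246 and 0.0452, and adjusted p = 0.85 in both with an estimated correlation. In young cells the Sertoli median was -0.13 with normexp background correction, and adjusted p = 0.0841 with slide as a term. Spermatogonial markers had a median of -0.23 in young cells, which was -0.0070 with normexp (adjusted p = 0.0428, adjusted p = 0.453 with an estimated correlation and adjusted p = 0.0996 with slide as a term).

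The effect of the antioxidant given before SIN-1 was tested as EUK-134 then SIN-1 minus SIN-1 alone (n = 4 and 4 in each age). The SIN-1 arrays are those compared with saline above, and they enter here with the opposite sign. Opposite shifts of a gene or list in these comparisons are therefore in part built in and do not show a reversal of the SIN-1 response. In young pachytene spermatocytes 2 features rose, 0 fell in limma, and 1570 had an unadjusted p under 0.05. Zfp352, a zinc finger gene, rose by 2.18 ± 0.37 (adjusted p = 0.0147), and the probe A_64_P097578 by 1.01 ± 0.16 (adjusted p = 0.00863, but -0.01 on the log2 scale with normexp background correction), each in 4 of 4 pairs. In aged cells 0 features passed, and 377 had an unadjusted p under 0.05. The smallest p there belonged to Lrg1 (-2.43 ± 0.44, adjusted p = 0.0634). Cflar, an inhibitor of caspase 8, had a value of 1.19 ± 0.23 (adjusted p = 0.0965). Without number 20, 21 or 22, no feature passed in young cells, and without number 24, 1 passed. No feature passed in young cells without slide 9, and in aged cells 2 passed without the array labelled young SIN-1 replicate 22. Without the array of the fewest probes above background, which is in the aged pretreated group, 4 passed in young and 1 in aged cells. The test of the difference between the ages gave 0 genes, with 189 at an unadjusted p under 0.05.

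With the title code as a block, 61 features rose and 17 fell in young cells after pretreatment, and 5 rose and 3 fell in aged cells. Slc2a1, the glucose transporter, rose by 1.64 ± 0.26 in young (adjusted p = 0.00216) and 1.64 ± 0.26 in aged cells (adjusted p = 0.00562). In young cells with the block the chemokine Cxcl2 (1.85), the protease Mmp3 (1.84), Egln3, a prolyl hydroxylase of the hypoxia response (1.62), Apold1 (1.40), Dusp1 (1.29), Il6 (1.05) and Ddit4 (1.02) also rose. In aged cells with the block Cflar (1.19), Tnfrsf1b, a receptor of tumour necrosis factor (1.11), and Podxl (0.98) rose. Lrg1 fell by 1.76 ± 0.24 in young (adjusted p = 0.00108) and 2.43 ± 0.24 in aged cells (adjusted p = 3.06e-06). Efna1 fell by 1.66 in young cells with the block, and Lpar6 fell by 1.37 in young and by 1.32 in aged cells. Adgrl4 (-1.87), Hspb3 (-1.14), Slc38a4 (-0.79), Lilra5 (-0.76) and Fbp2 (-0.63) fell in young cells with the block. The named genes moved in the same direction in 4 of 4 pairs, the pairs on which the block fit picked them. Over all the alternatives the adjusted p of Slc2a1 ran from 0.000135 to 1 in young and 0.000485 to 1 in aged cells, and that of Lrg1 from 0.000852 to 1 and 3.06e-06 to 1.

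The hypoxia and glycolysis list shifted with pretreatment in young cells, with a median of 0.16, 19 of 22 members above 0 and 5 past adjusted over the list alone (adjusted p = 0.000157, and adjusted p = 0.453 with an estimated correlation). In aged cells its median was 0.08, with 13 above 0 and 4 past adjusted over the list alone (adjusted p = 0.00175, adjusted p = 0.629 with an estimated correlation and adjusted p = 0.13 with slide as a term). Immediate early genes had medians of 0.27 and 0.20 in young and aged cells, with 15 and 18 of 23 above 0. Their adjusted p was 0.0398 and 0.00353, and adjusted p = 0.85 and 0.718 with an estimated correlation. With normexp background correction the median in young cells was 0.0388. The inflammation and NF-kB list had medians of 0.24 and 0.29, with 12 and 15 of 17 above 0. Its adjusted p was 0.00584 and 0.00382, and adjusted p = 0.85 in both with an estimated correlation. With normexp the median of this list in young cells was 0.0181. Nrf2 targets had medians of 0.16 and 0.13, with 16 and 18 of 20 above 0 (adjusted p = 0.0089 and 0.029, and adjusted p = 0.85 in both with an estimated correlation). Oxidative phosphorylation genes had a median of -0.12 in young cells, with 26 of 32 below 0 (adjusted p = 0.00255, and adjusted p = 0.85 with an estimated correlation), which turned to 0.0037 with quantile normalization and 0.0055 with the deposited matrix. In aged cells the unfolded protein and integrated stress response list had a median of 0.06 (adjusted p = 0.047, and adjusted p = 0.848 with an estimated correlation). Spermatogonial markers had a median of 0.18 there (adjusted p = 0.0246, and adjusted p = 0.418 with an estimated correlation), and adjusted p = 0.0577 with the title code as a block.

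The effect of the antioxidant alone was tested as EUK-134 minus saline at 17 h over both ages (n = 8 and 9). The saline arrays are those compared with SIN-1 above, so shifts shared with SIN-1 are not independent. In pachytene spermatocytes 7 features rose and 8 fell in limma, and 1156 had an unadjusted p under 0.05. Apold1, not well above background on any saline array, was at least 2.7-fold higher (adjusted p = 4.8e-06). Depp1, a target of FOXO factors, rose by 2.60 ± 0.42 (adjusted p = 0.00219) and Egln3 by 1.71 ± 0.23 (adjusted p = 0.000127). Slc16a3, a lactate transporter, rose by 1.28 ± 0.19 (adjusted p = 0.000374), Cflar by 0.91 ± 0.16 (adjusted p = 0.00581), Stc1, stanniocalcin, by 1.62 ± 0.34 (adjusted p = 0.0463) and Inhba, a subunit of activin, by 0.89 ± 0.19 (adjusted p = 0.0478). Lrg1 fell by 2.15 ± 0.30 (adjusted p = 0.000195), Adgrl4 by 1.60 ± 0.32 (adjusted p = 0.0369), Lpar6 by 1.09 ± 0.22 (adjusted p = 0.0425), the aminopeptidase Anpep by 1.07 ± 0.22 (adjusted p = 0.0425) and Angpt2, an angiopoietin, by 0.75 ± 0.14 (adjusted p = 0.0249). Ccn2, connective tissue growth factor, was not well above background on any EUK-134 array and was at least 2.75-fold lower (adjusted p = 0.0385). Stc1 and Anpep differed in this direction in 6 of 7 pairs, and the other named genes in 7 of 7. The endothelial markers Esam, Pecam1, Kdr and Cdh5 had log2 differences of 0.29 ± 0.21, -0.18 ± 0.25, -0.29 ± 0.20 and 0.10 ± 0.15.

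With the title code as a block, 25 features rose and 23 fell under EUK-134, Slc2a1 rose by 1.29 ± 0.19 (adjusted p = 0.000399), Cxcl2 by 1.49, Il6 by 1.07, and Esm1 fell by 2.01 ± 0.31 (adjusted p = 0.000962), each in 7 of 7 pairs. Over all the alternatives the adjusted p ran from 8.3e-06 to 0.728 for Slc2a1 and from 0.000962 to 0.831 for Esm1. The hypoxia and glycolysis list had a median of 0.08 (0.0341 with the deposited matrix), with 14 of 22 members above 0, 1 rise and 4 past adjusted over the list alone (adjusted p = 0.00248, and adjusted p = 0.629 with an estimated correlation). A fit with slide gave 7 rises and 5 falls, and 7 genes passed without slide 9. Leaving out number 20, 21, 22 or 23 gave 7, 6, 6 or 7 genes, and leaving out number 24 gave 772. Of the arrays compared, 6 of 8 under EUK-134 and 3 of 9 under saline were on slides 7 to 12. With number 24 left out, 6 of 6 under EUK-134 and 1 of 7 under saline were on these slides, and 4 genes passed with slide as a block, where slide and treatment largely overlap. Within young cells 0 genes passed in limma (390 at an unadjusted p under 0.05), and within aged cells 2 rose and 1 fell. With the block 4 rose and 6 fell in young cells, and 17 rose and 7 fell in aged cells. The test of the difference between the ages gave 0 genes, with 134 at an unadjusted p under 0.05. Against saline, EUK-134 followed by SIN-1 gave 7 rises and 1 fall in young cells and 6 rises and 1 fall in aged cells. With the title code as a block these counts were 36 and 20, and 28 and 9.

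**Figure D2:**
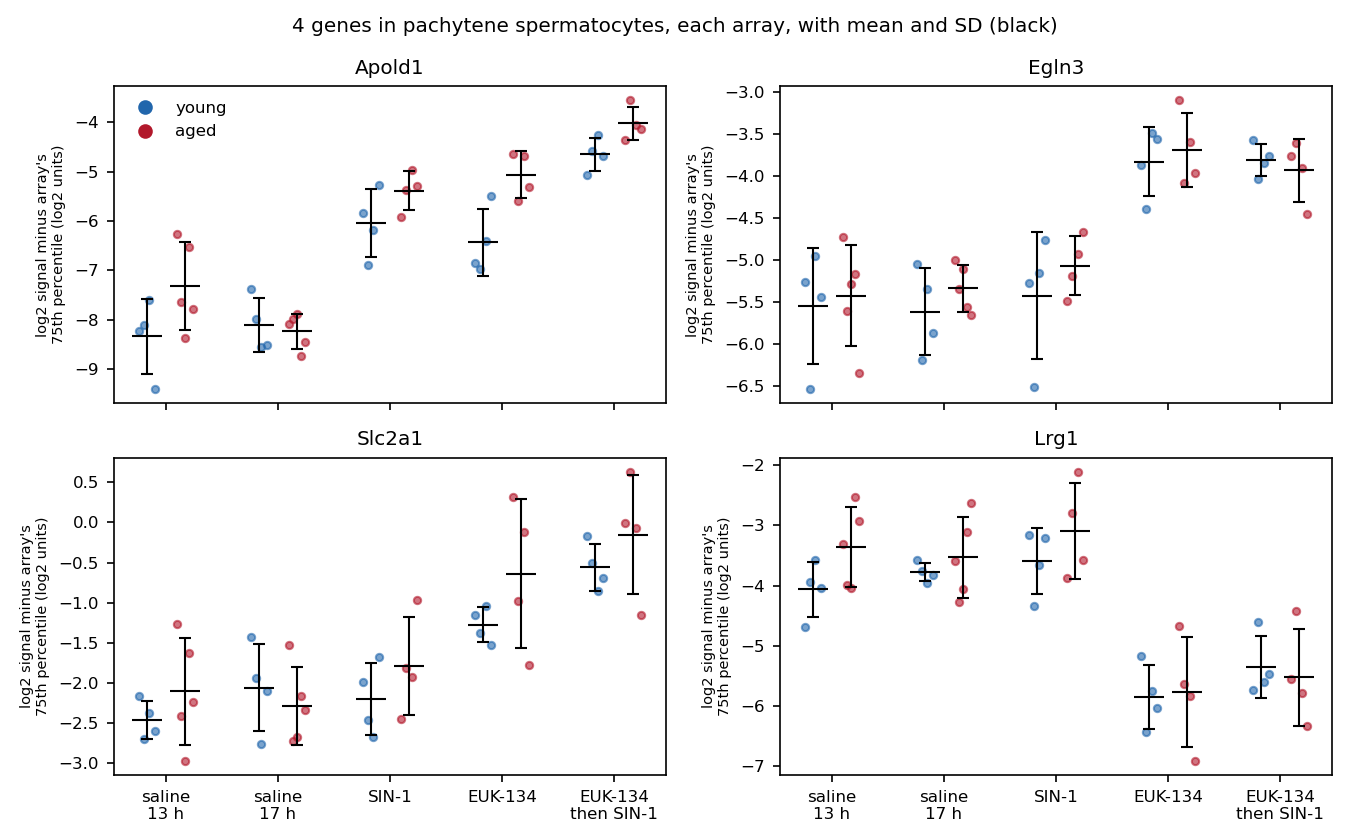
Normalised log2 level (vertical axis, log2 signal minus the 75th percentile of the array) of Apold1, Lrg1, Slc2a1 and Egln3 on each pachytene array, by condition (horizontal axis) and age (colour). Points are arrays and black marks are the mean and SD of a group of 4 or 5, and the mean of Apold1 is lowest under saline in both ages.

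The effect of 4 more hours in culture was tested as saline at 17 h minus saline at 13 h over both ages (n = 9 and 9). In pachytene spermatocytes 1 gene rose, 0 fell in limma, and 2046 had an unadjusted p under 0.05. Slc1a1, a glutamate transporter, rose by 0.58 ± 0.07 (adjusted p = 3.63e-05, 8 of 8 pairs). With the title code as a block, 302 features rose and 132 fell. Among the rises with the block were Ccl2 (0.76), Cryab, a small heat shock protein (0.79), Myc (0.72), Prdx1, a peroxiredoxin (0.46), and Sycp1, of the synaptonemal complex (0.42). Cyp11a1 and Cyp17a1, enzymes of steroid synthesis, fell by 1.26 ± 0.25 (adjusted p = 0.0116) and 0.68 ± 0.11 (adjusted p = 0.0063) with the block. Without the block the adjusted p of Cyp11a1 and Cyp17a1 was 0.425 and 0.52, and over the alternatives it ran from 0.00654 to 0.999 and from 0.00299 to 1. The genes named for the block moved in the same direction in 8 of 8 pairs, except Cyp11a1 in 7 of 8. Leydig cell markers had a median of -0.21 with 8 of 9 below 0 (adjusted p = 0.0305, adjusted p = 0.85 with an estimated correlation and adjusted p = 0.0621 with slide as a term). Double-strand break repair genes had a median of -0.07, with 16 of 21 below 0 (adjusted p = 0.0305, adjusted p = 0.453 with an estimated correlation and adjusted p = 0.0542 with the block). With normexp background correction these medians were -0.0801 and -0.0080. Without number 20, 2 genes passed, and with slide as a term 3 rose and 2 fell. The test of the difference between the ages gave 0 genes, with 176 at an unadjusted p under 0.05.

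**Figure D3:**
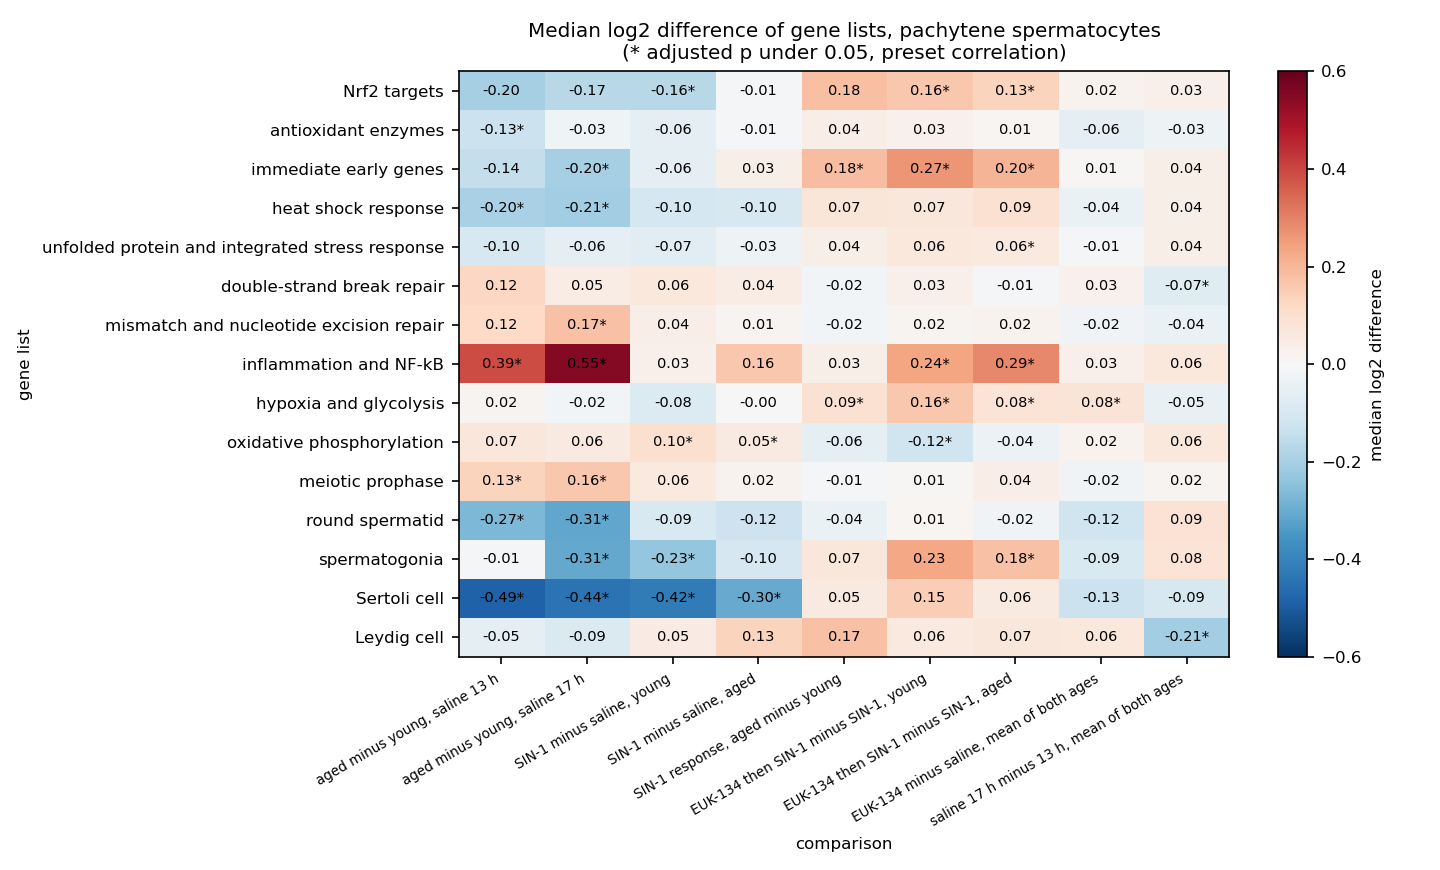
Median log2 difference (colour and printed value) of gene lists (vertical axis) in the pachytene comparisons (horizontal axis). Asterisks mark lists with adjusted p under 0.05 by camera with the preset correlation, and with an estimated correlation no list passes.

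In round spermatids the age comparison under saline at 13 h (n = 5 and 4) gave 1 rise and 2 falls among 21158 features in limma, with 944 at an unadjusted p under 0.05. Serinc2 fell by 4.03 ± 0.67 (adjusted p = 0.00844), Cxadr fell by 3.77 ± 0.60 (adjusted p = 0.0067) and Zcchc17 rose by 2.92 ± 0.53 (adjusted p = 0.0257). Without number 21, 22, 23 or 24, 0 genes passed. At 17 h 0 genes passed in limma, with 382 at an unadjusted p under 0.05, and Cxadr and Zcchc17 had values of -2.73 ± 0.60 and 2.22 ± 0.53, each with adjusted p = 1. Of the 3 spermatid arrays at the marker level of the other age, 1 belonged to the aged saline group at 17 h, and without these arrays 4 genes passed. These arrays were picked by the levels of age genes, so this count is not independent of the age result. Without number 23, which leaves out the same aged array, 2 genes passed. With slide as a term 1 gene rose and 5 fell at 13 h. Macrophage markers had a median of -0.77 at 13 h with 13 of 14 below 0 (adjusted p = 5.08e-05, and adjusted p = 0.932 with an estimated correlation). Markers of peritubular myoid cells and fibroblasts had a median of -0.45 (adjusted p = 0.0224, and adjusted p = 0.932 with an estimated correlation). The inflammation and NF-kB list had a median of 0.15 at 17 h (adjusted p = 0.0366, adjusted p = 0.932 with an estimated correlation and adjusted p = 0.0836 with slide as a term). With normexp background correction these medians were -0.31, -0.20 and 0.0772. Without the 3 arrays at the marker level of the other age the inflammation median was 0.29 (adjusted p = 0.0223). Without them the macrophage markers had a median of 0.0402 at 17 h (adjusted p = 0.768).

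For the treatments, 0 genes passed in round spermatids in limma, with or without the title code as a block. At an unadjusted p under 0.05 there were 1489 features for SIN-1 in young cells, 1042 for SIN-1 in aged cells, 742 for the interaction, 1049 and 369 for pretreatment in young and aged cells, 3848 for EUK-134 and 720 for culture time, against 1058 by chance. Under SIN-1 in young cells the smallest p belonged to Angptl6 (-0.90 ± 0.17, adjusted p = 0.119), Slc24a3 (-0.93 ± 0.20, adjusted p = 0.243) and Gss, glutathione synthetase (-0.47 ± 0.11, adjusted p = 0.369). In aged cells Exoc6b and Nxph3 had values of -1.76 and -1.48, and Slfn9, not well above background on any SIN-1 array, a bound of at least 2.07-fold lower, each with adjusted p = 0.799. Ccn2, not well above background after EUK-134 and SIN-1, had a bound of at least 4.48-fold lower than under SIN-1 alone in young cells, and did not pass (adjusted p = 0.943). The bounds in this paragraph do not allow for the spread between arrays. In aged cells after pretreatment Fzd2 and Lck had values of -0.68 and -0.34, and Ghrhr, not well above background on any pretreated array, a bound of at least 1.65-fold lower, each with adjusted p = 1. Under EUK-134 Adar, an RNA editing enzyme (-1.05 ± 0.21, adjusted p = 0.189), and Cybb, the catalytic subunit of the phagocyte NADPH oxidase (-1.20 ± 0.27, adjusted p = 0.221), were among the smallest p. With culture time Utf1, Cnrip1 and Fam20a had values of 0.59, 0.85 and 0.91, each with adjusted p = 0.999. Without number 21, 1 gene passed for SIN-1 in aged cells. Without number 22, 1 gene passed for EUK-134, and without number 24 there were 3719. In that case 6 of 6 EUK-134 arrays and 0 of 7 saline arrays were on slides 7 to 12, and 0 genes passed with slide as a block.

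Gene lists called with all spermatid arrays had adjusted p = 0.932 with an estimated correlation in each case that follows. Lists without the 3 arrays at the marker level of the other age were tested with the preset correlation only. Antioxidant enzymes had a median of -0.18 under SIN-1 in aged cells, with 23 of 25 below 0 (adjusted p = 0.0236), adjusted p = 0.57 with slide as a term, adjusted p = 0.0531 with the title code as a block and adjusted p = 0.0859 without the 3 arrays at the marker level of the other age. In the interaction of SIN-1 with age, the response of 7 lists was lower in aged than in young cells, among them peritubular markers (-0.29, adjusted p = 0.0224) and the proteasome (-0.12, adjusted p = 0.0417). Without these 3 arrays both had adjusted p = 0.0101 and 0.0197, and the other 5 lists passed no longer. The proteasome passed under SIN-1 in young cells only without these arrays (0.0893, adjusted p = 0.0458, against 0.114 with them). Only the peritubular list passed with slide as a term (adjusted p = 0.048), and the proteasome had adjusted p = 0.147, and adjusted p = 0.0531 with the title code as a block. The proteasome median was -0.0546 with normexp background correction. After pretreatment in young cells apoptosis machinery had a median of -0.16 and macrophage markers of -0.54, each with adjusted p = 0.0236, and without the 3 arrays adjusted p = 0.119 and 0.0433. Peritubular markers (-0.33, adjusted p = 0.0121) and the proteasome (-0.0988, adjusted p = 0.0458) passed there only without the 3 arrays, against adjusted p = 0.0746 and 0.17 with them. Apoptosis machinery had adjusted p = 0.0716 with slide as a term, and the macrophage median was -0.17 with normexp. In aged cells oxidative phosphorylation had a median of 0.06 and meiotic prophase of 0.07, each with adjusted p = 0.0444, and without the 3 arrays adjusted p = 0.0521 and 0.0458. They had adjusted p = 0.0613 and 0.054 with the title code as a block, and meiotic prophase had adjusted p = 0.148 with slide as a term. With culture time oxidative phosphorylation had a median of -0.09, with 26 of 32 below 0 (adjusted p = 1.06e-05), and the proteasome passed only without the 3 arrays (-0.0422, adjusted p = 0.0449). Endothelial and red blood cell markers had a median of 0.44 with 7 of 7 above 0 (adjusted p = 0.0236, and adjusted p = 0.0566 with slide as a term).

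The comparison of round spermatids with pachytene spermatocytes over all ages and conditions (n = 42 and 42) checked the cell type labels. Of 22164 features, 9345 rose and 9877 fell in limma. Each slide held 1 cell type, and all pachytene arrays were scanned on 1 day and all spermatid arrays on another, per the file headers. These differences therefore include any effect of scan day, which no fit here removes. With slide as a random block 8559 rose and 9234 fell. Among the falls were Pou5f2 (-5.78 ± 0.07), H1f6, the testis linker histone (-5.35 ± 0.08), Fbxo43, an inhibitor of the anaphase-promoting complex (-5.11 ± 0.07), Mlh3, a crossover protein (-3.95 ± 0.05), and Piwil1, of the piRNA pathway (-3.16 ± 0.08). Among the rises were Txndc2, a sperm thioredoxin (4.05 ± 0.07), Cabs1 (3.58 ± 0.07), Prdx4, a peroxiredoxin (3.34 ± 0.07), Pdk1 (3.22 ± 0.07), Tssk2, a testis kinase (3.17 ± 0.06), Capza3 (3.05 ± 0.06) and Ephx1, an epoxide hydrolase (2.86 ± 0.08). These genes differed in the same direction in 10 of 10 title codes. Of the 27 round spermatid markers 26 rose, with a median of 2.77 (adjusted p = 5.85e-14, and adjusted p = 0.409 with an estimated correlation). Oxidative phosphorylation had a median of -0.39, with 25 falls and 3 rises among 32 members (adjusted p = 0.00221, and adjusted p = 0.485 with an estimated correlation). The proteasome list had a median of -0.51 with 24 falls and 3 rises among 29 members (adjusted p = 0.00953, and adjusted p = 0.455 with an estimated correlation). The median over all features was -0.02 here, -0.13 with quantile normalization and 0.16 with normexp background correction.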

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

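Of the tests reported here, those on the 3 spermatid arrays, the test of slides for the EUK-134 genes the counts with slide as a term for the splits and the tests of neighbours by cluster were chosen only after the result was seen.

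On 3 round spermatid arrays the 4 features that part the ages in pachytene spermatocytes (Serinc2, Cxadr, Zcchc17 and the probe A_64_P038963) lay at the level of the other age. They are the arrays labelled aged saline 17 h replicate 23, young SIN-1 replicate 22 and young EUK-134 replicate 24, and each sat at row 2, column 3 of its slide. An exchange of labels among these arrays alone is argued against, since 2 of them had aged marker levels and 1 is labelled aged. An exchange with further spermatid arrays is argued against too, since the other 18 young and 21 aged spermatid arrays lay at the level of their labelled age. Pachytene samples on these 3 arrays are argued against by the mean level of the round spermatid markers, 5.07 to 5.10 on them and at most 2.81 on any pachytene array. The age markers were chosen to part all pachytene arrays, so their agreement with the labels of these is in part built in. Cyp2c7, which was not among the markers, was at -4.72 on the array labelled pachytene young SIN-1 replicate 22, within the aged range of -6.81 to -3.86. This pachytene array, too, sat at row 2, column 3 of its slide. On the markers, however, all 20 young pachytene arrays, this one included, lay apart from the aged ones. Serinc2 ran from -1.94 to -1.16 against -4.23 to -3.25, and Zcchc17 from -5.23 to -3.40 against -1.74 to -0.82. These levels argue against aged RNA alone on this array, though of 8 features called in both age comparisons only 4 parted all arrays. The median position of the markers of the 3 spermatid arrays was 0.9798 on a linear scale from the labelled age (0) to the other age (1). Single positions ran from 0.66 to 1.58. RNA of both ages mixed on single arrays is not excluded by this, since the arrays were picked by these markers. Labels that do not match the RNA remain open and untested: 12 of 12 marker values lay nearer to the mean of the other age and 10 within its range, but the arrays were picked by these values. Single wrong labels or samples from outside the series may underlie them. No biological explanation was tested.

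Serinc2, Zcchc17 and Cxadr parted young from aged in both cell types apart from the 3 arrays in doubt, and Serinc2 and Zcchc17 lie 2 genes apart on chromosome 5 and moved in opposite directions. A genetic difference between the young and the aged animals may contribute and stays open. Among 86 genes called by age with a place on the reference, 9 pairs lay within 10 genes of each other, against a mean of 3.56 in 10000 random draws (permutation p = 0.0112). The trio of Zcchc17, Ptpru and Serinc2 makes 3 of these pairs, and includes the pair that raised the idea. Without the trio 6 pairs remained against a mean of 3.30 (permutation p = 0.113), and with each cluster counted once there were 7 against 3.33 (permutation p = 0.0394). Some of these pairs, such as Ccl2 with Ccl7 and Hspe1 with Hspd1, are neighbours known to be regulated together, so shared regulation stays open as well. A sequence variant under single probes cannot be told apart from a change in transcript level, because the array holds 0 other probes of these genes. Age itself stays open and untested, since the series holds no other strain or cohort.

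The EUK-134 genes in pachytene spermatocytes include Apold1, Adgrl4, Angpt2 and Ccn2, which are known from endothelial and stromal cells. A change in the share of endothelial cells as the cause of the falls is argued against by the endothelial markers Esam, Pecam1, Kdr and Cdh5, whose median log2 difference was -0.0418 (standard error of their mean 0.13), against -1.26 for the 8 features that fell. This standard error is taken over the 4 genes and is no spread between arrays. Slides as the whole cause are argued against, since 9 of the 15 features also passed with slide as a term. A change in the share of stromal or other cells was not checked in this way and stays open. A response of the germ cells, or of another cell type in the fraction at a constant share, may also underlie these genes, and no test here parts these.

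Other groupings of the same arrays were counted for each comparison. The share of splits with as many genes, the real one included, was set against 0.05. These shares were not corrected over the comparisons, so a share under 0.05 does not by itself exclude chance. Where the real grouping gave 0 genes, every split gives as many, so that share was fixed in advance and tests nothing. In pachytene spermatocytes the share lay under 0.05 for age at 13 h (1 of 100 splits gave as many genes, the real one with 12 and the highest other with 5), age at 17 h (1 of 100, 99 and 3), pretreatment in young cells (1 of 35, 2 and 1) and EUK-134 (1 of 100, 15 and 0). For pretreatment this rests on 2 genes against 1. The share was at least 0.05, and chance cannot be excluded, for SIN-1 in young cells (5 of 35, 1 and 25), SIN-1 in aged cells (6 of 100, 1 and 2070), the interaction (100 of 100, 0 and 460), pretreatment in aged cells (35 of 35, 0 and 1) and culture time (5 of 100, 1 and 2). With the title code as a block and groupings within codes, 1 of 8 splits gave as many genes for SIN-1 in young cells (104, highest other 1), pretreatment in young cells (78 and 4) and pretreatment in aged cells (8 and 0), and 8 splits are too few for a share under 0.05. With this block the share lay under 0.05 for culture time (1 of 100, 434 and 0) and narrowly for EUK-134 (3 of 64, 48 and 5988). For EUK-134 another split gave many more genes than the real one, so chance stays open there. In round spermatids the share lay under 0.05 for age at 13 h (2 of 100, 3 and 295), but another split gave many more genes than the real one, so chance stays open. Chance cannot be excluded for age at 17 h (100 of 100, 0 and 4), SIN-1 in young (35 of 35, 0 and 48) and aged cells (100 of 100, 0 and 2291), the interaction (100 of 100, 0 and 2457), pretreatment in young (35 of 35, 0 and 291) and aged cells (35 of 35, 0 and 0), EUK-134 (100 of 100, 0 and 3667) and culture time (100 of 100, 0 and 74). For the cell types the share lay under 0.05 (1 of 100, 19222 and 6098).

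Within a cell type, several splits with many genes divided the arrays mostly by slide. The split with 2070 genes set 0 of 4 arrays on slides 7 to 12 against 5 of 5, that with 5988 set 8 of 8 against 1 of 9, and that with 3667 set 1 of 8 against 8 of 9. With slide as a term these 3 splits gave 0 genes, as did the spermatid splits with 295, 48, 2291, 2457 and 291, and the pachytene split with 460 gave 2. The spermatid split with 74 genes gave 170 with slide as a term, so slide does not account for it. Where a split follows the slides, few arrays inform the fit with slide as a term, and a count of 0 there does not show the size of the slide effect. In pachytene spermatocytes the real grouping and the split with the highest other count gave, with slide as a term, 166 and 6 genes for age at 13 h, 278 and 26 for age at 17 h, 3 and 5 for SIN-1 in young cells, 1 and 0 for SIN-1 in aged cells and 0 and 2 for the interaction. They gave 5 and 3 for pretreatment in young cells, 1 and 0 in aged cells, 12 and 0 for EUK-134 and 5 and 0 for culture time. In round spermatids they gave 6 and 0 for age at 13 h, 0 and 3 for age at 17 h, 0 and 170 for culture time and 0 and 0 for the others.

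In 520 tests of groups for an array far from the others, 23 stood out by Dixon's ratio, where chance flags about 1 in 20 (26 in all). The array labelled spermatid aged EUK-134 replicate 20 had the highest 75th percentile of log2 signal of its group (10.61, next 9.78), and the lowest mean level of base excision repair genes (0.0176). All ranks here are within the 4 or 5 arrays of a group. Among pachytene arrays the mean normalised log2 level of a list stood lowest in its group for Nrf2 targets in aged EUK-134 replicate 22 (-1.21), for the unfolded protein and integrated stress response in aged saline 13 h replicate 22 (0.0667) and aged saline 17 h replicate 22 (0.19), for meiotic prophase in young saline 17 h replicate 24 (1.75) and for Leydig markers in aged saline 17 h replicate 22 (-2.70). It stood highest in its group for apoptosis machinery (-1.06) and cholesterol synthesis (0.0727) in young EUK-134 then SIN-1 replicate 24, for mismatch and nucleotide excision repair in young EUK-134 replicate 23 (-0.13), for hypoxia and glycolysis in young saline 17 h replicate 20 (0.0732), for the proteasome in young EUK-134 replicate 24 (2.75), for meiotic prophase in aged EUK-134 replicate 24 (2.25) and for macrophage markers in aged SIN-1 replicate 23 (-4.00). Among spermatid arrays it stood lowest in its group for antioxidant enzymes in aged saline 13 h replicate 24 (-0.33), for the proteasome in aged saline 13 h replicate 20 (1.98), for cholesterol synthesis in aged saline 17 h replicate 20 (-0.45) and for Sertoli markers in young EUK-134 replicate 24 (-2.69). It stood highest in its group for inflammation and NF-kB in young EUK-134 replicate 23 (-0.98), for meiotic prophase in young EUK-134 replicate 24 (1.49), for round spermatid markers in aged SIN-1 replicate 21 (5.14), and for peritubular markers in aged EUK-134 then SIN-1 replicate 21 (-2.63) and young EUK-134 then SIN-1 replicate 22 (-2.29). The spermatid array labelled young EUK-134 replicate 24 is among those at the age-marker level of the other age, so its label is in doubt.

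The SIN-1 response of 9 lists differed between the ages by the interaction, with adjusted p = 0.629 and 0.85 for the pachytene lists and 0.932 for the spermatid lists with an estimated correlation. In pachytene spermatocytes the median interaction was 0.18 for immediate early genes (adjusted p = 0.0182) and 0.0932 for hypoxia and glycolysis (adjusted p = 0.00407). In round spermatids it was -0.21 for antioxidant enzymes (adjusted p = 0.0444), -0.39 for immediate early genes (adjusted p = 0.0444), -0.22 for apoptosis machinery (adjusted p = 0.0236), -0.0868 for oxidative phosphorylation (adjusted p = 0.0451), -0.12 for the proteasome (adjusted p = 0.0417), -0.69 for macrophage markers (adjusted p = 0.0451) and -0.29 for peritubular markers (adjusted p = 0.0224). Without the 3 arrays the spermatid peritubular and proteasome lists had adjusted p = 0.0101 and 0.0197, and the other 5 no longer passed: antioxidant enzymes 0.166, immediate early genes 0.0958, apoptosis machinery 0.207, oxidative phosphorylation 0.0521 and macrophage markers 0.106. Peritubular markers (0.00611) and apoptosis machinery (0.0402) passed with the title code as a block and the other 5 did not, and only peritubular markers passed with slide as a term (0.048). With normexp background correction the median was -0.0250 for oxidative phosphorylation and -0.0546 for the proteasome in round spermatids, and 0.0533 for immediate early genes in pachytene spermatocytes.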

How the results depend on the processing

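The alternatives chosen after seeing the data are the replicate block with slide, leaving out slide 9, the pachytene array labelled young SIN-1 replicate 22, the pachytene array of the fewest probes above background or the 3 spermatid arrays, and slide as a block with number 24 left out. Counts of genes stayed within 1.5 times the reported count in 239 cases and moved further in 104. The 239 include cases where no gene passed in the reported fit or under the alternative, such as the pachytene interaction with normexp. The spermatid treatments gave such cases too, for example with slide as a block. These cases do not show that a count of called genes is stable. Of the named genes, 4584 values kept direction and side of the threshold, 354 passed only under the alternative, 295 no longer passed and 15 changed sign. The 56 list calls were each rerun under 3 or 4 alternatives, where 94 kept their side of the threshold and 94 lost it, 56 of these with the estimated correlation. The counts that moved are given in the order age 13 h, age 17 h, SIN-1 young, SIN-1 aged, pretreatment young, pretreatment aged, EUK-134 and culture time of pachytene spermatocytes, where moved. The cause was not tested unless stated.

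Normexp gave 36 and 35 for age, 0 and 0 for SIN-1, 0 and 1 for pretreatment and 5 for EUK-134. Signs changed with normexp for Rab11fip1 under SIN-1 in young cells (0.12), for Ctbs (-0.0448) and Dusp14 (-0.0948) in the pachytene interaction, for St8sia5 (-0.0165) and the probe A_64_P097578 (-0.0103) with pretreatment in young cells, and for Il1b (0.0859), Anxa10 (0.10), Vil1 (0.0109), Zkscan1 (0.0266) and Oit3 (0.12) with culture time. In round spermatids they changed for Fas under SIN-1 in aged cells (-0.10) and, in the interaction, for Manea (-0.23), Or2g7 (-0.19), Or1e21b (-0.22) and Fas (-0.10). The median over all spermatid features in this interaction was 0.01, and -0.17 with normexp. Quantile normalization and the deposited matrix each gave 19 for age at 13 h, 0 and 2 for SIN-1, 2 for pretreatment in aged cells, 7 for EUK-134 and 2 for culture time. No filter on dim probes gave 5 and 47 for age, with more features tested. Only the groups compared gave 4 and 17 for age, 0 for SIN-1 and 0 for pretreatment in young cells, 8 for EUK-134 and 2 for culture time, with fewer arrays for the spread. At least 1.5-fold gave 0 for culture time.

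Slide as a block gave 166 and 278 for age, 3 for SIN-1 in young cells, 5 and 1 for pretreatment, 5 for culture time and 6 for spermatid age at 13 h. Slide and array row gave 94 and 220, 4 and 2, 11 and 1, 9 for EUK-134, 4 for culture time and 5 for spermatid age at 13 h. The replicate block (pairing by title code, or by number for age) gave 451 and 383 for age, 104 for SIN-1 in young cells, 78 and 8 for pretreatment, 48 for EUK-134 and 434 for culture time. The replicate block and slide gave 954 and 646, 243 and 4, 893 and 57, 60, 1083, and 5 for spermatid age at 13 h. Without slide 9 there were 56 for age at 17 h, 11 for SIN-1 in young cells, 0 and 1 for pretreatment, 7 for EUK-134 and 3 for culture time. Without the array labelled young SIN-1 replicate 22, picked for its level of the age gene Cyp2c7 and its few probes above background, there were 31 and 143 for age, 2 for SIN-1 in young cells and 2 for pretreatment in aged cells. Without the array of the fewest probes above background there were 4 and 1 for pretreatment and 2 for culture time, and age at 13 h stayed within 1.5 times with 10. Without the 3 spermatid arrays, picked by the levels of age genes, 4 genes passed for spermatid age at 17 h. This count is not independent of the age result.

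Leaving out each number in turn gave 5 to 13 and 6 to 62 genes for age, 0 to 1 and 1 to 1 for SIN-1, 0 to 1 for the interaction, 0 to 2 and 0 to 0 for pretreatment, 6 to 772 for EUK-134 and 1 to 2 for culture time in pachytene spermatocytes. In round spermatids it gave 0 to 3 and 0 to 2 for age, 0 to 0 and 0 to 1 for SIN-1, 0 to 0 for the interaction, pretreatment and culture time, and 0 to 3719 for EUK-134. For the cell types it gave 18473 to 18727. The 772 and 3719 came without number 24 and were 4 and 0 with slide as a block. Without number 24, EUK-134 and saline arrays shared 1 slide in pachytene spermatocytes and 0 in round spermatids, so these counts do not tell slide from treatment. Genes near background were limited by signal: bounds replace folds where 0 arrays of the lower group were well above background.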

Other observations

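The lists of metal handling, p53 targets, base excision repair and cholesterol synthesis passed in 0 of the 19 comparisons by camera. The smallest adjusted p of metal handling was 0.0803, for EUK-134 in pachytene spermatocytes (median -0.15). For p53 targets it was 0.188, for pachytene age at 17 h (-0.07), for base excision repair 0.277, for pachytene culture time (-0.06), and for cholesterol synthesis 0.0767, for the cell types (-0.51). In aged pachytene spermatocytes at 17 h Plk3 and Bbc3, of the p53 targets, had values of -0.97 ± 0.25 (adjusted p = 0.0591) and -1.05 ± 0.27 (adjusted p = 0.0592). Cyp51 and Msmo1, of cholesterol synthesis, had values of -0.80 ± 0.20 (adjusted p = 0.0502) and -0.77 ± 0.21 (adjusted p = 0.0756).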
